A study of Mus musculus with 5 samples.

How the data were processed

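Hi-C, which joins and sequences pieces of DNA that lie close together in the nucleus, was made from sorted neuronal nuclei of the mouse hippocampus. Nuclei were stained for NeuN, a protein of neuronal nuclei, and for GFP, and sorted by flow cytometry, per the labels' protocols. The mice carried a tamoxifen-dependent Cre recombinase driven by Arc, an immediate early gene of active neurons, and a floxed yellow fluorescent protein reporter, so neurons active around a dose of 4-hydroxytamoxifen stay labelled. That dose was given before contextual fear conditioning, in which a context is paired with a foot shock. Libraries were prepared from 100000 nuclei per group, collected from 2 animals, with a commercial Hi-C kit, per the labels' protocols. The 5 libraries were grouped by their titles into Basal (2 libraries), Early (1 library) and Late (2 libraries). The treatment label is the same for all 5 libraries (foot shock and tissue collection on day 0, no recall), although the protocol describes collections 1.5 to 2 h and 5 days after conditioning. The times behind Basal, Early and Late are therefore taken only as far as the titles state them. A further Early library was not analysed here.

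Each library came as 1 table of the first principal component (PC1) of its interaction matrix. The deposited PC1 values are a signed score per bin, made with HOMER on the mouse build mm9, per the submitters' processing notes. The versions, the aligner and the read filters are not given in the sources used here. The bins are 50 kb long and the PC1 was computed in windows of 100 kb, so neighbouring bins share reads. On each chromosome analysed the values of each library were centred near 0 with an SD of 1.00 to 1.01, so the overall strength of compartments cannot be compared between libraries. In HOMER's convention a positive PC1 marks compartment A (open, gene-rich chromatin) and a negative one compartment B (closed, gene-poor chromatin). How the authors set that sign is not given in the sources used here. The last bin of chromosome 1 ended at 197200000. Coordinates are given 1-based in mm9. The files hold no read counts, so the depth is unknown and no counting interval can be given.

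Of 51811 bins listed in any library, 50542 had a value in all 5. The analysis was limited to autosomes and X chromosomes on which every pair of libraries correlated with a Pearson r of at least 0.5 over bins. Chromosome 7 failed this rule with a lowest r of -0.976. The other 18 autosomes and X gave 47652 bins (2382.6 Mb). A bin's PC1 was compared between groups with limma 3.58.1 in R 4.3.3, on the values as deposited, with all 5 libraries in 1 fit, 2-sided tests and Benjamini-Hochberg adjustment over bins at 0.05. The fit had 2 residual degrees of freedom, to which the prior shared over bins added 6.60. The lone Early library is assumed to vary like the Basal and Late libraries. The p-values measure the spread between libraries of a group, and neighbouring bins are not independent. Whether the libraries of a group came from separate animals or separate pools of nuclei is not stated. The p-values can therefore not be read as measuring the spread between animals. Compartment switches were counted without a test, as bins with 1 sign in all libraries of a group and the opposite sign in all libraries of the other. That count was set beside the counts from the other ways to split the same libraries, for each of the 3 comparisons. Correlations are across bins, which are not independent replicates. The rule for named regions merged called bins of the same direction across a gap of at most 1 bin. It took the 10 regions per direction and comparison with the largest mean difference over their called bins, 60 in all. Local noise per library was estimated from the differences between libraries, as the deviation of each bin from the mean of the bins 100 kb on either side. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest.

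The fit was tested on simulated PC1 values for the 47652 bins. With 4750 bins changed by 0.5 and 4750 by 1, the Late versus Basal fit recovered 63.7% and 99.1% of them, and the Early versus Basal fit 34.5% and 95.6%. With 100 bins changed by each amount, Late versus Basal recovered 0% and 65.0%, and Early versus Basal recovered none of either size. With no change and each library given its own local noise, the fit called 0 bins for Late versus Basal, 278 for Early versus Basal and 666 for Late versus Early. These draws were independent between bins, with 1 SD per library, and hold no deviations that run over many bins. They therefore do not give the number of false calls in the real data. Choices of test, filter, region rule and most alternatives were made before the data were examined. The alternatives were 3 other scalings (quantile normalization, the SD of each chromosome and, for switches, its median), other sets of bins, a trend in the prior, a replicate block, a looser threshold and leaving out each library. Removal of a 10 Mb trend, weighting by local noise, chromosome 7 with its sign inverted, the autosomes without 16 and 19, the 2 scalings of the share of A, and the autosomes for the correlation of changes were added after seeing the data. So were the simulations of shared calls and of shared switches, each with 100 draws of unchanged groups. Tests of gene lists, planned for an annotation of the same build, were not run, because the gene table used here is on another mouse assembly (GRCm38.p6). No gene is named for that reason.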

Results

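PC1 of the Hi-C matrix was compared in hippocampal neuronal nuclei of 3 states named Basal, Early and Late, to ask how the division of the genome into A and B compartments differs between states of neurons after fear conditioning. The Basal libraries listed 51695 and 51726 bins, the Early library 50558, and the Late libraries 51558 and 50790. Outside unplaced sequence of chromosome Y they listed between 50529 and 50785 bins each. On that sequence the Basal libraries listed 910 and 943 bins, Early 29, Late replicate 1 931 and Late replicate 2 187. Local noise was 0.115 and 0.119 PC1 units in the Basal libraries, 0.205 in Early, 0.101 in Late replicate 1 and 0.188 in Late replicate 2.

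Libraries of 1 group were more alike than libraries of different groups. Across bins, PC1 correlated with a Pearson r of 0.986 between the Basal replicates (Spearman's rho 0.985) and 0.967 between the Late replicates (rho 0.966). The 4 pairs of a Basal with a Late library gave r from 0.917 to 0.935. Early correlated least, with r of 0.889 and 0.892 to Basal and of 0.909 and 0.917 to Late. On X, r was 0.973 between the Basal replicates and 0.959 between the Late replicates. It was 0.745 to 0.800 between Basal and Late and 0.639 to 0.642 between Basal and Early, but 0.938 to 0.939 between Early and Late. In the 18 autosomes, the lowest r was 0.882 between a Basal and a Late library and 0.732 between a Basal library and Early.

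Compartment A held 47.2% of bins in each Basal library, 49.0% in Early, and 48.2% and 48.5% in the Late libraries. With 2, 1 and 2 libraries these shares are given without a test. The order depended on the scaling: with chromosome medians aligned, the shares were 47.9% in each Basal library, 47.9% in Early, and 48.2% and 48.0% in Late. Aligned medians bring the shares together by construction. Runs of neighbouring bins of 1 sign numbered 1995 in Late replicate 1, with a mean length of 1194 kb, and 3127 in Early, with a mean length of 762 kb. Basal replicates 1 and 2 had 2498 and 2463 runs, and Late replicate 2 had 2907. The number of runs went with local noise: Late replicate 1 had the lowest (0.101), and Late replicate 2 (0.188) and Early (0.205) the highest. The counts are therefore not read as a difference between states.

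The comparison of Late with Basal asks which parts of the genome sit in another compartment environment in the Late state. In limma, 7819 of 47652 bins (16.4%) passed an adjusted p of 0.05, of which 4184 were higher in Late, toward A, and 3635 lower, toward B. Their median difference was 0.607 PC1 units for the higher bins (median SE 0.127) and 0.630 for the lower bins (median SE 0.126). The higher bins formed 1190 regions, and the longest spanned 2850 kb. The lower bins formed 932 regions, and the longest spanned 6350 kb. Of the higher bins 1108 (26.5%), and of the lower bins 996 (27.4%), also had opposite signs in all Basal and all Late libraries. By position, 66.8% of the higher bins lay in compartment B by their Basal mean, and 34.1% of the lower bins. Over all bins, 47.2% lay in compartment A in each Basal library. Calling bins by Late minus Basal itself favours low Basal values among higher bins and high ones among lower bins. The autosomes alone gave 5979 bins, 3238 higher and 2741 lower. With all sequences kept as deposited, including chromosome 7, limma called 0 bins (13365 at an unadjusted p under 0.05). In each comparison this setting leaves the differences of the analysed bins unchanged. It alters only the variance shared over bins and the set of bins adjusted over. With chromosome 7 alone added and its sign inverted in Late replicate 1, limma called 8543 bins. The count also rested on the libraries used: it was 2641 without Basal replicate 1, 2842 without Basal replicate 2 and 14390 without Late replicate 1.

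The strongest autosomal rise lay on chromosome 18 from 57150001 to 57500000, where PC1 went from -0.33 ± 0.037 in Basal to 0.83 ± 0.14 in Late (SD, n = 2 each), a difference of 1.15 (limma adjusted p at most 0.0195 in its 7 bins). Chromosome 13 from 63450001 to 64250000 rose from -0.26 ± 0.029 to 0.83 ± 0.16 (SD, n = 2 each), with Early at 0.73. The other 8 named rises were all on X, at 102.60 to 102.95 Mb (difference 1.14), 137.60 to 138.20 Mb (1.12), 159.40 to 160.10 Mb (1.12), 139.55 to 139.90 Mb (1.07), 103.45 to 105.90 Mb (1.07), 149.85 to 150.40 Mb (1.06), 73.25 to 74.75 Mb (0.98) and 146.50 to 146.80 Mb (0.98). The labels do not give the sex of the mice. On X, a different sex of the animals can therefore not be told apart from a different state. The same limit holds for the X regions named below.

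Among the named falls, 4 were autosomal. Chromosome 16 from 5300001 to 7200000 fell from 1.08 ± 0.050 in Basal to 0.019 ± 0.0075 in Late (SD, n = 2 each), near the border of A and B, although this call was lost when a 10 Mb trend was removed (difference -0.53). Chromosome 14 from 39100001 to 40300000 fell from 0.29 ± 0.065 to -0.76 ± 0.13 (SD, n = 2 each), passing from A to B, with Early at 0.00095. Chromosome 16 from 75100001 to 75400000 fell from -0.059 ± 0.10 to -1.08 ± 0.0058 (SD, n = 2 each). Chromosome 13 from 14300001 to 14650000 fell from 0.54 ± 0.0083 to -0.47 ± 0.090 (SD, n = 2 each), with Early at -0.37. The other 6 named falls were on X, at 17.50 to 20.70 Mb (difference -1.33), 166.45 to 166.50 Mb (-1.22), 6.80 to 7.85 Mb (-1.16), 13.25 to 17.40 Mb (-1.08), 56.15 to 56.50 Mb (-1.06) and 35.80 to 40.85 Mb (-1.02). With the trend removed, the X regions at 146.50 Mb (difference 0.39), 17.50 Mb (-0.43), 13.25 Mb (-0.30) and 35.80 Mb (-0.42) were no longer called. The other 7 named X rises kept their call with smaller differences, from 0.49 at 139.55 Mb to 0.73 at 102.60 and 159.40 Mb. The region at 166.45 Mb is the last bin of X, and its Late replicates lay apart, at 0.42 and -0.56.

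**Figure D1:**
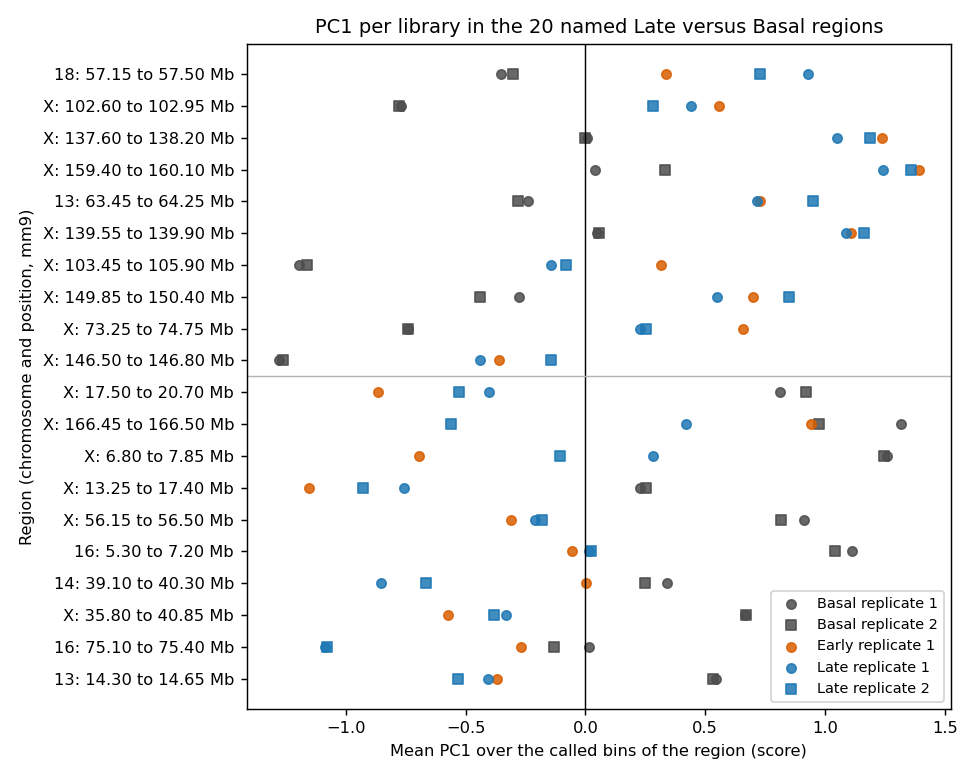
Mean PC1 (score, x axis) over the called bins of each of the 20 named Late versus Basal regions (y axis, chromosome and mm9 position), with 1 point per library; circles are replicate 1 and squares replicate 2. The 10 regions above the grey line rose and the 10 below it fell. The Basal and Late points do not overlap in any of them, which follows from choosing the regions by this difference.

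Changed bins were unevenly spread over chromosomes. X had the highest share in Late versus Basal, with 1451 of its 3002 bins called (48.3%), and still with a 10 Mb trend removed (25.4%). Among autosomes the share ran from 7.33% on chromosome 11 to 23.6% on chromosome 18, with a median of 14.1%. On X the direction depended on position. Of the bins proximal to 72.80 Mb, 666 were lower and 109 higher in Late, and of the bins distal to it, 625 were higher and 51 lower. The mean PC1 of the distal part minus that of the proximal part was -0.35 and -0.34 in the Basal libraries, 0.77 in Early, and 0.41 and 0.50 in Late replicates 1 and 2. Beside this, the bins listed on unplaced Y sequence numbered 910 and 943 in Basal, 29 in Early, and 931 and 187 in Late. The position 72.80 Mb was chosen from these data, as the best single step of the Early minus Basal change.

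**Figure D2:**
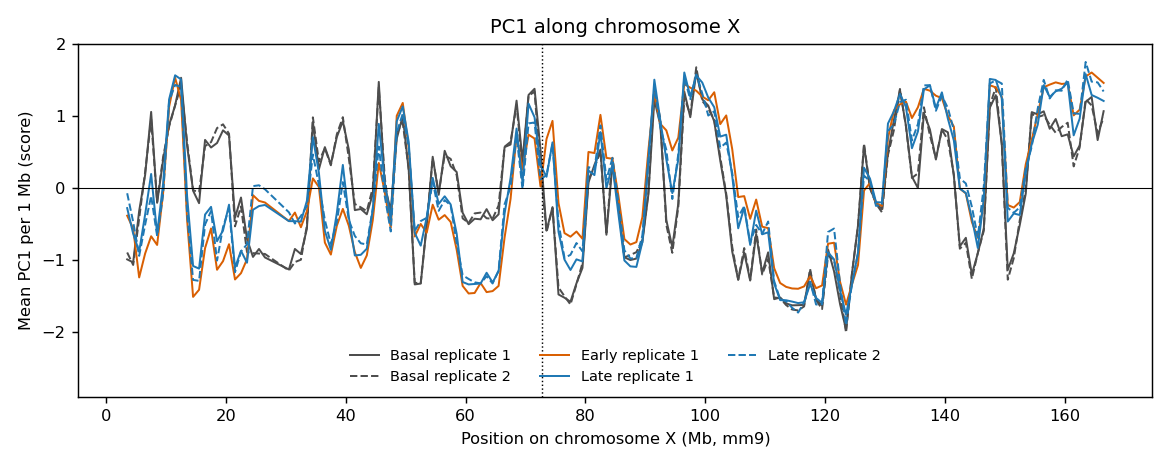
PC1 (score, y axis) averaged in steps of 1 Mb along chromosome X (x axis, Mb in mm9), with 1 line per library: solid for replicate 1 and dashed for replicate 2. Left of the dotted line at 72.80 Mb the Early and Late lines run mostly below Basal, and right of it mostly above.

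Counting signs alone, 2740 bins (5.75%) lay in 1 compartment in both Basal libraries and in the other in both Late libraries. Of these, 1493 passed from B to A and 1247 from A to B. The other ways to split the 4 libraries into pairs gave 180 and 130 bins. These splits count only bins on which the replicates of both groups have opposite signs. Replicates that agree keep such counts low by construction, whatever sets the groups apart. B to A made up 54.5% of switched bins as deposited. It was 48.9% with chromosome medians aligned between libraries and 47.4% with quantile-normalized values, so the majority depended on the scaling. Aligned medians and quantile normalization bring the shares of A together, so a near balance of switches follows by construction. Switched bins lay near the border, with a median absolute Basal PC1 of 0.261 for B to A and 0.319 for A to B. Requiring each library to pass 0 by 0.1 SD left 1441 bins, and leaving out Late replicate 1 gave 4138. The longest run from B to A spanned 750 kb on chromosome 4 from 55650001 to 56400000, with PC1 of -0.34 and -0.39 in Basal and 0.45 and 0.35 in Late. The longest run from A to B spanned 2250 kb on X from 36300001 to 38550000, with PC1 of 0.43 and 0.42 in Basal and -0.78 and -0.71 in Late.

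**Figure D3:**
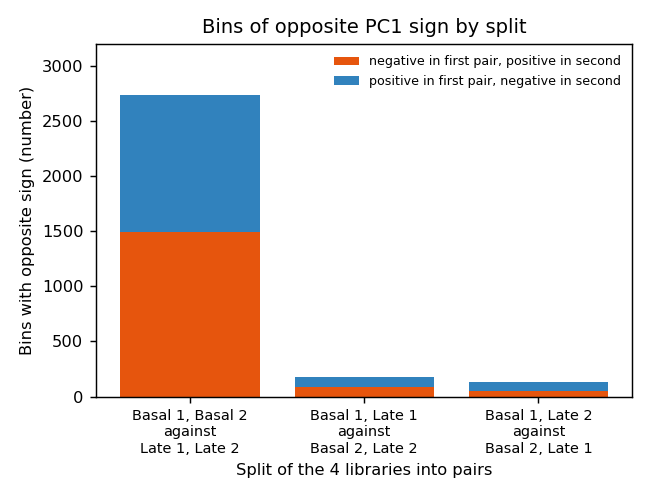
Number of 50 kb bins (y axis) whose PC1 has 1 sign in both libraries of a pair and the opposite sign in both libraries of the other pair, for the 3 ways to split the Basal and Late libraries (x axis); colours give the direction. The split by group gives 2740 bins and the crossed splits 180 and 130. Crossed splits need opposite signs within both groups, so their counts are low by construction where replicates agree.

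The comparison of Early with Basal asks the same of the Early state, from 1 library. In limma 9503 bins (19.9%) passed, 4749 higher and 4754 lower in Early, with a median difference of 0.738 for the higher (median SE 0.155) and 0.740 for the lower bins (median SE 0.154). Chromosomes 16 (43.8% of bins), 19 (43.6%) and X (52.1%) held the highest shares, against a median of 17.2% over the 18 autosomes and 7.28% on chromosome 11. With a 10 Mb trend removed, the shares were 20.1% on chromosome 16, 14.9% on chromosome 19 and 27.4% on X, and chromosome 13 led the autosomes with 22.8%. Weighted by local noise, which is highest in Early, the fit called 3503 bins. With all sequences as deposited limma called 2084. It called 4248 without Basal replicate 1, 4493 without Basal replicate 2, and 17853 without either Late library.

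Among named rises, chromosome 13 from 70750001 to 74050000 went from -0.27 ± 0.010 in Basal (SD, n = 2) to 1.08 in Early, a difference of 1.35 (limma adjusted p at most 0.0306 in its 63 bins). The other autosomal rises were on chromosome 15 at 27.00 to 27.15 Mb (difference 1.33) and 6.75 to 7.20 Mb (1.23), chromosome 12 at 119.75 to 119.85 Mb (1.33), chromosome 10 at 44.55 to 44.65 Mb (1.27) and chromosome 16 at 92.75 to 93.55 Mb (1.26). X rose at 103.40 to 105.90 Mb (1.479), 102.60 to 102.95 Mb (1.33), 93.15 to 95.90 Mb (1.31) and 131.75 to 131.85 Mb (1.23). The longest named fall was on chromosome 19 from 38750001 to 47900000, from 0.59 ± 0.0028 in Basal (SD, n = 2) to -0.65 in Early, with Late at 0.55 ± 0.031 (SD, n = 2). Chromosome 16 fell at 30.75 to 37.95 Mb (difference -1.36), 98.15 to 98.20 Mb (-1.28), 10.60 to 10.80 Mb (-1.27) and 5.70 to 7.15 Mb (-1.25). X fell at 17.70 to 20.70 Mb (-1.80), 6.55 to 7.85 Mb (-1.80), 8.35 to 8.55 Mb (-1.46), 13.25 to 17.40 Mb (-1.39) and 47.85 to 48.00 Mb (-1.39). With a 10 Mb trend removed, 4 of these 20 regions were no longer called: chromosome 19 at 38.75 Mb (difference -0.25), chromosome 16 at 30.75 Mb (-0.31) and 5.70 Mb (-0.44), and X at 13.25 Mb (-0.36). With all sequences as deposited, the calls on chromosome 12 at 119.75 Mb and chromosome 16 at 10.60 Mb were lost, with unchanged differences of 1.33 and -1.27.

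By sign, 4662 bins (9.78%) of the Early library were opposite to both Basal libraries, 2714 in A and 1948 in B. The other splits of these 3 libraries set 1 Basal library against the other Basal library and Early, and gave 798 and 962 bins. They need the Basal replicates to differ in sign, so the agreement of those replicates keeps these counts low by construction. Single Late libraries compared with the same Basal pair gave 3704 and 4138 bins. The share in A was 58.2% as deposited and 49.7% with chromosome medians aligned, so the majority toward A depended on the scaling. Aligned medians bring the shares of A together, so a near balance of switches follows by construction. The longest run from B to A spanned 2250 kb on chromosome 13 from 71150001 to 73400000, with PC1 of -0.55 and -0.53 in Basal and 0.91 in Early.

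The comparison of Late with Early asks where the later state differs from the Early one. In limma 6062 bins (12.7%) passed, 2991 higher and 3071 lower in Late. Chromosomes 19 (40.2%) and 16 (35.0%) held the highest shares, while X, with 5.63%, lay near the lowest autosome (5.14%, chromosome 11). With a 10 Mb trend removed, chromosome 16 had 16.2%, chromosome 13 15.0%, chromosome 18 11.7% and chromosome 19 11.1%. Weighted by local noise, 1072 bins passed, and with all sequences as deposited limma called 0 (12635 at an unadjusted p under 0.05). The count was 3799 without either Basal library, 11020 without Late replicate 1 and 12608 without Late replicate 2.

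The named rises were led by chromosome 13 from 74450001 to 74600000, at -1.40 in Early and 0.023 ± 0.21 in Late (SD, n = 2), with Basal at -0.33 ± 0.023 (SD, n = 2). The others were on chromosome 18 at 7.60 to 7.70 Mb (difference 1.40), chromosome 19 at 43.50 to 48.00 Mb (1.36), chromosome 14 at 123.00 to 123.10 Mb (1.35), chromosome 16 at 32.20 to 37.15 Mb (1.34), 8.65 to 8.85 Mb (1.32) and 30.70 to 31.50 Mb (1.22), chromosome 15 at 82.05 to 82.75 Mb (1.30) and 77.20 to 77.55 Mb (1.27), and chromosome 13 at 103.10 to 103.20 Mb (1.26). The named falls lay on chromosome 15 at 27.00 to 27.15 Mb (-1.43), 26.55 to 26.70 Mb (-1.35), 11.40 to 11.50 Mb (-1.30) and 52.95 to 53.05 Mb (-1.21), on chromosome 16 from 50000001 to 50200000 (-1.30) and at 74.65 to 75.00 Mb (-1.19), on chromosome 18 at 45.35 to 45.40 Mb (-1.26), on chromosome 13 at 69.30 to 69.40 Mb (-1.26) and 9.80 to 11.05 Mb (-1.19), and on chromosome 12 at 119.75 to 119.85 Mb (-1.23). Removing a 10 Mb trend ended the calls on chromosome 19 at 43.50 Mb (difference 0.45), chromosome 16 at 32.20 Mb (0.34) and 30.70 Mb (0.26), chromosome 15 at 82.05 Mb (0.67) and chromosome 12 at 119.75 Mb (-0.88), and weighting by local noise ended those on chromosome 13 at 103.10 Mb (1.13) and chromosome 12 at 119.75 Mb (-1.06). By sign, 3602 bins of the Early library were opposite to both Late libraries. Of these, 1649 were in B in Early and A in Late, and 1953 the reverse. The majority toward B depended on the scaling: the counts were 1777 and 1727 with chromosome medians aligned, and 1761 and 1793 with quantile normalization. Both of these scalings bring the shares of A together, so near-equal counts follow by construction. The splits that set 1 Late library against the other Late library and Early gave 1236 and 1436 bins. They need the Late replicates to differ in sign, so the agreement of those replicates keeps these counts low by construction.

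**Figure D4:**
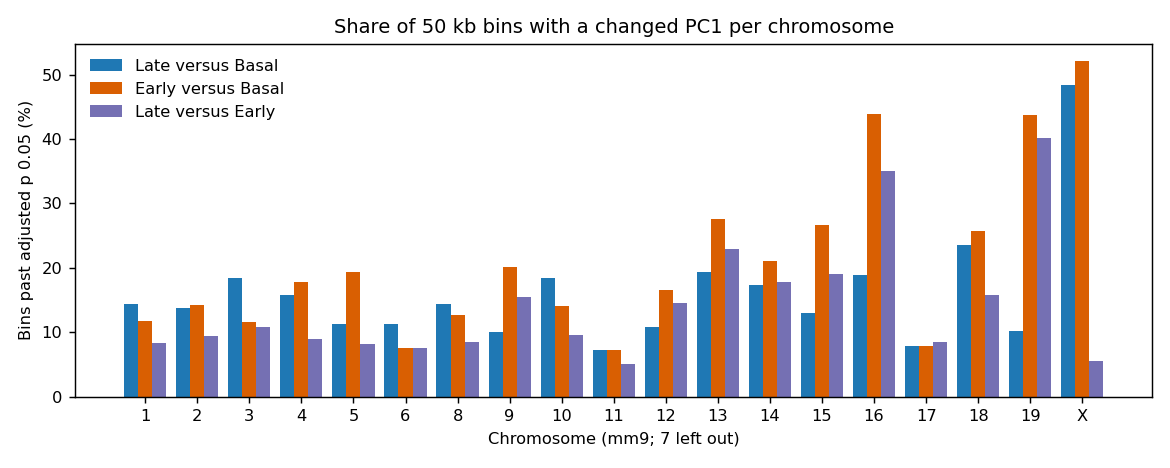
Share of tested 50 kb bins past an adjusted p of 0.05 in limma (y axis, %) on each chromosome (x axis, mm9), with 1 bar per comparison. X is high in both comparisons with Basal (48.3% and 52.1%) and low in Late versus Early (5.63%), and chromosomes 16 and 19 are high in both comparisons that hold the Early library.

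The Early and Late changes from Basal were also set against each other. Of the called bins, 1880 were higher in both and 1446 lower in both, where independent lists of those lengths would share 417 and 363. In opposite directions, 61 bins were higher in Early and lower in Late, and 55 the reverse, against 362 and 417. On the autosomes 1267 bins were higher in both and 792 lower in both, against 306 and 260.1 for independent lists. Both comparisons share the Basal libraries. In 100 simulations of unchanged groups against shared controls, lists of the same lengths, taken as the bins of smallest p in limma, shared a mean of 1308 bins higher in both and 1185 lower in both, and 115.6 and 134.1 in opposite directions. The observed 1880 and 1446 lay above the highest simulated counts (1376 and 1249), and the observed 61 and 55 below the lowest (87 and 104). On the autosomes the simulated lists shared 1039 and 928.0. The 1267 autosomal bins higher in both lay above the simulated range of 981 to 1096. The 792 lower in both lay below that of 882 to 977. The simulated groups hold no real change, so these ranges cannot show how many bins real but unrelated changes would share. No conclusion is drawn from counts above or below them. Across all bins the changes correlated with r = 0.55 (rho 0.49), where simulated unchanged groups gave 0.26. Their covariance was 0.0895 against 0.00688 simulated, and on the autosomes, a setting added after seeing the data, 0.0610 against 0.00642. The difference from the simulated covariance was 0.0826 (jackknife SE of the observed covariance over chromosomes 0.0291), and on the autosomes 0.0546 (SE 0.00545). With 1 Basal library for each change, r was 0.48 and 0.49 and the covariance 0.0819 and 0.0834. Anything common to both Basal libraries, such as their preparation, enters both changes. Neither the simulation nor the split of the Basal libraries removes it. The difference is therefore not given as the part shared by the Early and Late states. The shared calls were not counted with split controls. Shared libraries alone gave more same-direction bins than independent lists did, so the number of shared calls in excess of either is not given as the size of a shared effect.

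Of the 2714 bins that were in B in Basal and A in Early, 966 (35.6%) were in A in both Late libraries and 43.1% were in B in both. Of the 1948 bins that were in A in Basal and B in Early, 669 (34.3%) were in B in both Late libraries and 48.1% were in A in both. Bins that had not switched in Early, matched on their Basal PC1, switched in Late in 10.3% and 8.58% of cases. In 100 simulations of unchanged groups that shared the Basal libraries, 16.7% and 17.7% of Early switches were found in both Late libraries, against 4.92% and 5.48% of matched bins, from a mean of 527 and 504 Early switches. The matched share therefore does not remove the effect of the shared libraries. On the autosomes 33.8% of switches to A and 27.3% of switches to B in Early were found in both Late libraries, against 11.5% and 9.68% of matched bins and a simulated 16.8% and 17.7%. The observed shares, for all bins and for the autosomes, lay above the highest of the 100 simulations. That was 20.9% and 21.9% for all bins and 21.2% in both directions for the autosomes. The simulated groups hold no real change and switched in fewer bins. They cannot show how many switches real but unrelated changes would share.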

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

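The tests on X and on chromosome 7 in this part were chosen after the result was seen; those on chromosomes 16 and 19 were set before their outcome was known. Dixon's test for outliers was not applied, because groups of 1 or 2 libraries are too small for it.

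Chromosome X set Basal apart from all 3 other libraries. Higher noise of those libraries is argued against: Late replicate 1 has the lowest local noise of all, yet its r with Basal replicate 1 on X was 0.80, below every autosome analysed (lowest 0.906). A single step explained 36.6% of the Late minus Basal change along X, at 72.85 Mb, and 42.3% of the Early minus Basal change, at 72.80 Mb, while the best autosome reached 18.3% (chromosome 16) and 34.5% (chromosome 19). A candidate explanation is a different share of female nuclei, since the inactive X of females folds into 2 large parts. The sex of the mice was not given in the labels. The low numbers of bins on unplaced Y sequence in Early (29) and Late replicate 2 (187) go with it. Late replicate 1, with 931 such bins like Basal, had a step of 0.759 against 0.845 in Late replicate 2. That library does not decide the question, because nuclei came from 2 animals per group. The number of bins listed does not give the share of nuclei with a Y chromosome. A difference between the states themselves, or between preparations, was not tested and stays open, because each state has its own libraries.

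Early stood apart on chromosomes 16 and 19, where its r with Basal replicate 1 was 0.734 and 0.74, against at least 0.847 on the other 16 autosomes. With a 10 Mb running mean removed, r was 0.828 and 0.892, within the range of the other autosomes (0.810 to 0.945). Chromosome 16 stayed below all of these except chromosome 13 (0.810). The rise in r goes with a gradient broader than 10 Mb that enters the component of this library. Bin-to-bin noise is argued against, since the higher of the local noise values on these chromosomes was 0.285, inside the range of 0.160 to 0.303 on the others. Whether the gradient reflects the Early state or this preparation stays open with 1 Early library.

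Chromosome 7 was left out of the comparisons by the rule on r and used in 2 alternatives. In Late replicate 1, 88.3% of its bins had the sign opposite to both Basal libraries, against 8.31% in Late replicate 2 and 5.78% in Early. With the sign inverted, r with Late replicate 2 was 0.976, within the range of the other autosomes (0.946 to 0.979), and 10.6% of bins were opposite to Basal. Inverting the values only changes the sign of r, so 0.976 follows from the r of -0.976 as deposited and is not separate support. A sign set the other way when the file was made is a candidate explanation; an exchange of all compartments in 1 replicate was not excluded by a test.

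In 11 of the named regions of the comparisons with Basal, the Late change differed from the Early change by limma's test of Late against Early (median adjusted p under 0.05 over the region's bins); 9 of them had been chosen for the size of the Early change, which favours such a difference, and Early is 1 library. With all sequences as deposited limma called 0 bins for Late versus Early (12635 at an unadjusted p under 0.05), and chromosome 12 at 119.75 Mb also lost its call with noise weights and with the 10 Mb trend removed. Late lay below Early on chromosome 14 at 39.10 to 40.30 Mb (difference -0.761), chromosome 16 at 75.10 to 75.40 Mb (-0.814) and 92.75 to 93.55 Mb (-0.831), chromosome 13 at 70.75 to 74.05 Mb (-0.847), chromosome 15 at 27.00 to 27.15 Mb (-1.43), chromosome 12 at 119.75 to 119.85 Mb (-1.23) and X at 131.75 to 131.85 Mb (-0.607). Late lay above Early on chromosome 16 at 30.75 to 37.95 Mb (1.21), 98.15 to 98.20 Mb (1.21) and 10.60 to 10.80 Mb (1.12), and on chromosome 19 at 38.75 to 47.90 Mb (1.20). On chromosome 16 at 30.75 Mb and chromosome 19 at 38.75 Mb, the Early versus Basal calls were lost with the 10 Mb trend removed. So were the calls of the Late versus Early regions that overlap them. Outside the chromosomes analysed, Late replicate 1 reached a PC1 of 14.6 on unplaced Y sequence, where the highest values of the Basal libraries were 2.64 and 2.79.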

How the results depend on the processing

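The 10 Mb trend, the noise weights, chromosome 7 with its sign inverted, the autosomes without 16 and 19, the scalings of the share of A, and the autosomes for the correlation of changes were alternatives chosen after seeing the data. With all sequences as deposited, which includes chromosome 7, limma called 0 bins for Late versus Basal (13365 at an unadjusted p under 0.05), 2084 for Early versus Basal and 0 for Late versus Early (12635 unadjusted). With chromosome 7 alone added and its sign inverted it called 8543, 9644 and 7191; the unplaced sequences were not tested on their own. Every second bin gave 3999, 4831 and 3204 calls from 23822 bins, a count lower by construction. Leaving out bins near 0 gave 3613 for Late versus Basal, and an adjusted p under 0.1 gave 11999, 14428 and 10609. Removing the trend gave 5650 for Early versus Basal and 3341 for Late versus Early, weighting gave 3503 and 1072, and the autosomes without 16 and 19 gave 6100 for Early versus Basal; for these the cause was not tested. Leaving out 1 library gave 2641 to 14390 calls for Late versus Basal, 4248 to 17853 for Early versus Basal and 3799 to 12608 for Late versus Early, with a lone library assumed to vary like the others. Sign switches fell to 1441, 2796 and 2009 with a margin of 0.1 SD and to 1582, 2790 and 1804 in runs of at least 3 bins, both stricter by construction, and leaving out 1 library gave 3458 to 4138 for Late versus Basal. The rise in the share of A over Basal was 1.15 percentage points in Late and 1.86 in Early; it was 1.67 and 1.57 with all sequences and 1.41 and 2.27 on the autosomes. Quantile normalization sets it to 0 in both by construction, and with chromosome medians aligned it was 0.171 in Late and -0.0472 in Early, so its direction in Early reversed; aligned medians bring the shares together by construction. The mean r of Basal with Late was 0.926, and 0.937 on the autosomes. All other alternatives kept these counts within 1.5 times. None of the 60 named regions changed direction, and all 40 of those with Late against Basal or Early lost their call with all sequences as deposited, as did 2 of the 20 with Early against Basal, while their differences stayed the same. With the replicate block the fit called 8752, 9585 and 5818 bins; deviations of same-numbered Basal and Late libraries correlated at 0.0101, so the numbers were not read as pairs. The gene-list alternatives were not run. The files give no depth, and with 1 Early library its own spread is not measured.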

Other observations

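The autosomes differed in how much of them changed. Chromosome 11 had the lowest share of called bins in all 3 comparisons, at 7.33% for Late versus Basal, 7.28% for Early versus Basal and 5.14% for Late versus Early. In Late versus Basal, 13 of the 18 autosomes had more higher than lower calls, and in Early versus Basal 7 of 18. More bins switched from B to A than from A to B on 11 of 18 autosomes in Late and on 16 of 18 in Early, with values as deposited. With chromosome medians aligned, 48.9% of all Late switches and 49.7% of all Early switches went from B to A. A near balance follows from that scaling by construction. On X, 23.9% of the bins proximal to 72.80 Mb lay in A in Early, 33.5% and 32.8% in the Late libraries, and 57.4% and 56.7% in the Basal libraries. Of the distal bins 61.6% lay in A in Early, 57.5% and 58.4% in Late, and 45.9% and 46.9% in Basal.

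On chromosome Y itself, outside the comparisons, the 48 bins with a value in all libraries correlated with r = 0.936 between the Basal replicates and 0.896 and 0.927 between Basal and Late replicate 1. Early correlated with the Basal libraries at -0.0685 and -0.213, and Late replicate 2 at 0.111 and 0.225.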
